A study of Mus musculus with 4 samples.

How the data were processed

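Single-cell RNA sequencing libraries of hepatic CD45+ cells were compared between 2 exercise and 2 sedentary samples. Per the labels' protocols, livers were digested with collagenase, non-parenchymal cells were separated from hepatocytes by centrifugation and a Percoll gradient, CD45+ cells were selected with magnetic beads, and libraries were made with a 10x Genomics single-cell kit for a target of 6000 cells. The deposited values are UMI counts per gene and barcode, as whole numbers that were not normalized. Per the submitters' processing notes they were made with Cell Ranger, whose version is not given in the sources used here, and with Seurat 3.1, on the mouse genome mm10 (GRCm38). The series text describes alignment to a pre-mRNA genome, so counts may include intronic reads, and whether strand was used in counting is not given in the sources used here. How barcodes were called as cells is not given in the sources used here either. The lowest total per barcode was 1056 and 1126 UMIs in the exercise and 931 and 1008 in the sedentary libraries, so barcodes with fewer UMIs were already left out, and free RNA could not be measured in empty droplets.

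Each library listed the same 27998 genes, paired with Ensembl identifiers. Coordinates were taken from the GENCODE annotation of GRCm38, in which all 163 genes followed by name matched by identifier. Ighm, Ighd, Igha, Iglv1, Trac, Trbc1, Trbc2, Trdc, Tcrg-C1, Tcrg-C2, Pclaf, Mx2, Itgam, Flvcr1 and Firre were not used, because the symbols were not listed or were shared by several entries. Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 0, 6, 27 and 9 barcodes for UMIs or genes and 74, 43, 137 and 104 for mitochondrial share in exercise replicates 1 and 2 and sedentary replicates 1 and 2. Some barcodes failed both limits and count in each number, and 2917, 4221, 4026 and 3856 barcodes were left. Doublets were scored per library against 2 simulated doublets per cell, by the share of simulated doublets among the nearest neighbours, and the highest-scoring cells were removed at a rate of 0.8% per 1000 cells. This removed 68, 143, 130 and 119 cells (460 in all), which left 14560 of 15383 barcodes.

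Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 20 nearest neighbours were used for Leiden clustering at resolution 1.0 with seed 1, on the merged libraries without integration (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). The 26 clusters were named by hand from fixed marker lists into 17 classes, and a class is called "like" its cell type because the name rests on these markers alone. Kupffer-like cells are 5 clusters with leading genes such as C1qb, Clec4f, Folr2 and C1qc. In clusters 4 and 17 of this class, erythroid markers had a larger mean log2 fold over other cells (4.55 and 2.66) than Kupffer markers (1.03 and 0.86). Of 6 erythroid markers, 0 were detected in 10% of the cells of either cluster. An unnamed cluster with Kupffer and hepatocyte transcripts and the cycling Kupffer clusters were kept apart from this class, a decision made after seeing the data. No authors' annotation of cells was used here.

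Cells are not replicates, so counts were summed per library and class and tested across the 4 libraries. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling and the quasi-likelihood F-test of exercise against sedentary without covariates, and with Benjamini-Hochberg adjustment at 0.05. Each class with at least 20 cells in every library was fitted on its own. Log2 CPM values had a prior count of 2. Standard errors were taken from the fitted change and its F statistic. Numbers of cells per class were tested with the same edgeR test, with the number of kept cells as the offset, beside exact binomial 95% intervals and an exact permutation test. For these numbers TMM was left out and the spread was estimated over the classes without a trend over abundance. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 36 lists, and again with an estimated correlation and with fry.

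Genes to be named in Kupffer-like cells were set by rule: up to 12 genes per direction past the test with the largest change, a mean of at least 20 CPM and separated groups, filled up to 5 by smallest p where fewer passed, up to 4 members per gene list by smallest p, and 24 focus genes. In the other classes up to 3 genes per direction with the smallest adjusted p were named. Names outside the rule (Trf, Hbb-bt, Hba-a2, Pik3ip1, Ptpn22, Slpi, Il7r, Gzma, Gm8369, Hspa1a, Ahsg, Fabp1, the glucocorticoid-induced genes, and Zfp36l2 and H3f3b in B-like cells) were chosen after their values were seen. The hepatocyte list held 10 markers. Trf is also expressed by macrophages, so UMIs per cell were counted over the 9 others, which was decided after seeing the data.

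The tests were tested on simulated data drawn from the means and library sizes of the real libraries. In Kupffer-like cells (9840 genes), 13.4% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 12 false among 122 calls. Camera found a simulated shift of the lysosome list with the preset correlation (adjusted p = 1.49e-18). With the estimated correlation it missed this shift (adjusted p = 0.907). The simulated data were drawn from means and library sizes, not from the correlation between genes in the real lists. They therefore cannot show whether the preset correlation suits the real lists.

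Alternatives were a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, RLE factors, no filter on low counts, a minimum change of 1 on the log2 scale, thinning to the shallowest library, doublets kept, at most 10% mitochondrial UMIs, at least 1000 UMIs and 500 genes, Leiden resolutions of 0.5 and 2.0, variable genes and centring per library, cells with at least 3 of 6 Kupffer markers whatever their cluster, shares among named immune classes, and TMM over classes. Added after seeing the data were all Kupffer clusters, Kupffer clusters 0 and 1 only, Kupffer-like cells without hepatocyte marker UMIs, removal of the 1 percent of barcodes with the most hepatocyte marker UMIs, thinning of every Kupffer-like cell to 1500 UMIs, and crossed replicate numbers. Alanine aminotransferase was not tested against expression and was not used as a covariate here. It differed more between replicate numbers (26 and 33 against 59 and 56 U/L) than between groups. Figures were drawn with matplotlib 3.10.9.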

Results

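CD45+ leukocytes were isolated from the livers of wild-type C57BL/6 mice and profiled by droplet-based single-cell RNA sequencing, in which every cDNA carries a cell barcode and a unique molecular identifier (UMI), so that RNA molecules are counted. The exercise group (2 libraries) had run on a motorized treadmill at 12.5 m/min. The sedentary group (2 libraries) had been placed on a treadmill that did not move. Both did so for 60 min a day, 5 days a week, over 4 weeks. The series title names the question as whether exercise before surgery changes the inflammatory state and the metabolism of Kupffer cells, the resident macrophages of the liver. Serum alanine aminotransferase, an enzyme released by injured hepatocytes, was 26 and 59 U/L in exercise replicates 1 and 2 and 33 and 56 U/L in sedentary replicates 1 and 2. The labels do not say that the replicates are separate animals, although each has its own alanine aminotransferase value, so every p measures the spread between samples.

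The 4 libraries held 2991 and 4265 barcodes after exercise and 4165 and 3962 in the sedentary group, with 10050976, 14849778, 10662091 and 11826183 UMIs in the same order. After filtering, 2849, 4078, 3896 and 3737 cells remained, with a median of 2717, 2846.5, 2028 and 2382 UMIs and 1206, 1235, 963 and 1073 genes per cell. Hepatocyte transcripts differed between the groups over all kept cells, at 95.1 and 76.2 CPM (UMIs scaled to a library total of 1e6) after exercise against 771 and 392 CPM in the sedentary libraries for 9 markers such as albumin. Hemoglobin transcripts of red blood cells stood at 47.6 and 130 CPM against 2194 and 367 CPM. Mitochondrially encoded transcripts made up 4.72% and 4.61% of UMIs against 5.35% and 4.89%.

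Kupffer-like cells were the largest class in every library. The share of neutrophil-like cells was the only share of a named class past the test, lower after exercise, and this call was lost in several alternatives. Kupffer-like cells made up 42.8% ± 0.682 (SD, n = 2) of the kept cells after exercise and 33.8% ± 1.48 (SD, n = 2) in the sedentary group. Neutrophil-like cells, short-lived granulocytes recruited to injured tissue, made up 0.491% ± 0.346 (SD, n = 2) against 1.34% ± 0.484 (SD, n = 2). Their cluster had neutrophil markers at a mean log2 fold of 6.63 over other cells, with 8 of 9 detected in 10% of its cells. Basophil or mast cell markers stood at 2.88 there, with 1 of 8 detected, so the class may also hold such cells. B-like cells, the antibody-producing lineage, made up 11.03% ± 2.32 against 18.2% ± 4.08, and T-like cells 17.3% ± 3.08 against 16.4% ± 1.15. Plasmacytoid dendritic (pDC)-like cells, known for type I interferon production, made up 3.96% ± 0.681 against 2.68% ± 0.598.

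The comparison of shares asked whether the makeup of the CD45+ fraction differed between the groups. In edgeR's quasi-likelihood test on cell numbers, 2 of 18 classes passed after Benjamini-Hochberg adjustment. The neutrophil-like share fell by 1.37 on the log2 scale (SE 0.401, adjusted p = 0.0288), with both exercise libraries (7 and 30 cells) below both sedentary libraries (39 and 63 cells). In single libraries the neutrophil-like share was 0.246% (exact binomial 95% interval 0.0988 to 0.506) and 0.736% (0.497 to 1.05) after exercise and 1.00% (0.713 to 1.37) and 1.69% (1.30 to 2.15) in the sedentary group. The intervals cover counting error only. With at least 1000 UMIs and 500 genes per cell the groups no longer separated (5 of 2844 and 23 of 4068 cells after exercise, 12 of 3700 and 39 of 3690 in the sedentary group; log2 difference −0.81, adjusted p = 0.497 in edgeR). Neutrophil-like cells had a median of 1118, 1318.5, 1090 and 1148 UMIs, close to the lowest totals per barcode, which differ between libraries (1056, 1126, 931 and 1008). The call was also lost with doublets kept (adjusted p = 0.289 in edgeR), at resolution 0.5 (0.267), with centring per library (0.276) and among named immune classes (0.184). It was lost without exercise replicate 1 (edgeR adjusted p = 0.0769), without sedentary replicate 1 (adjusted p = 0.137) and without sedentary replicate 2 (adjusted p = 0.683). Over all alternatives of edgeR's test its adjusted p ran from 0.00144 to 0.683.

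The Kupffer-like share did not pass edgeR's test (log2 difference 0.34, adjusted p = 0.776), although both exercise libraries (43.3%, 95% interval 41.5 to 45.2, and 42.3%, 40.8 to 43.9) lay above both sedentary libraries (32.7%, 31.3 to 34.2, and 34.8%, 33.3 to 36.4). edgeR's test of shares drew its spread largely from all classes together. The SE was 0.290 for the Kupffer-like, 0.296 for the B-like and 0.293 for the T-like share. Its p, also for neutrophil-like cells, therefore does not measure the spread of a single share between samples. The B-like share (log2 difference −0.73, adjusted p = 0.114) and the pDC-like share (0.57, adjusted p = 0.378) did not pass either. Without exercise replicate 1 they did, at adjusted p = 0.0086 and 0.0355, against ranges over all alternatives of 0.0086 to 0.998 and 0.0355 to 0.998 in edgeR's test. The cycling Kupffer-like share (3.66% against 2.91%, log2 difference 0.35, adjusted p = 0.776) passed without exercise replicate 1 (0.81, adjusted p = 0.023) and was −0.39 without exercise replicate 2. Endothelial (LSEC)-like cells, from the sinusoid lining, made up 6.13% against 6.04%, NK or ILC-like cells 2.83% against 3.12%, conventional dendritic cDC1-like cells 2.22% against 2.37% and cDC2-like cells 1.33% against 1.41%. Classical monocyte-like cells made up 1.68% against 1.96% and other macrophage-like cells 1.47% against 1.35%. The other call belonged to an unnamed cluster with Kupffer and hepatocyte transcripts, which held 2.86% ± 0.467 (SD, n = 2) of cells after exercise and 5.64% ± 0.482 (SD, n = 2) in the sedentary group. Its size is not compared further, because the transcripts that define it differ between the groups. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333.

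**Figure D1:**
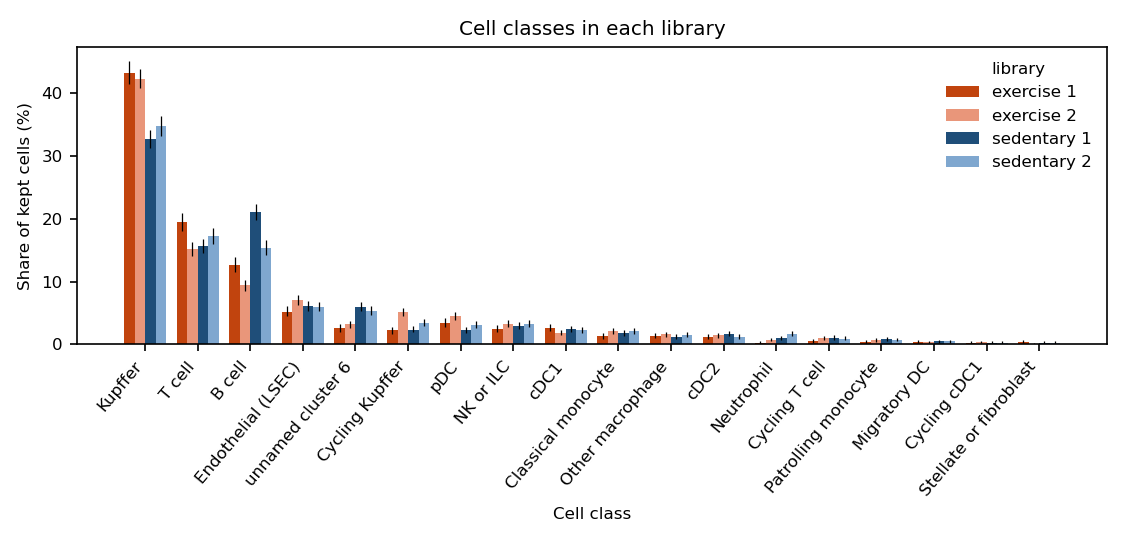
Share of kept cells (y axis, %) in each cell class (x axis) for the 4 libraries, with bars for single libraries and lines for exact binomial 95% intervals, which cover counting error only. Kupffer-like cells make up 43.3% and 42.3% in the exercise libraries and 32.7% and 34.8% in the sedentary ones.

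The central comparison was of Kupffer-like cells (5537 cells, 3307985 to 5837741 UMIs per library). Of the 36 genes that fell after exercise, 33 encode liver-secreted or other hepatocyte proteins, with log2 changes from −4.48 to −1.36 and a median of −3.17. Albumin (Alb), the main plasma protein made by hepatocytes, fell by 3.23 on the log2 scale, from 276 ± 124 to 29.8 ± 9.38 CPM (SD, n = 2). The other 3 genes that fell were Tnfaip3, whose product A20 restrains NF-kB signalling, the immediate early transcription factor Egr1, and Nfkbiz, an inducible NF-kB cofactor. Rsrp1, which encodes an arginine- and serine-rich protein, was the only gene that rose, from 269 ± 26.0 to 596 ± 125 CPM (SD, n = 2). In the 4 libraries, the 9 hepatocyte markers reached 0.523 and 0.393 UMIs per Kupffer-like cell after exercise and 3.36 and 2.18 in the sedentary group.

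Among the genes that fell were the plasma proteins hemopexin (Hpx, log2 change −3.61), Serpina3k (−3.30), transthyretin (Ttr, −2.94) and haptoglobin (Hp, −2.91), and the apolipoproteins Apoa1 (−3.03), Apoa2 (−2.74) and Apoc3 (−2.24). The major urinary proteins Mup3 (−2.82), Mup20 (−2.50) and Mup7 (−1.96) and the protease inhibitor Serpina1c (−2.29) fell as well. The 4 Mup and 5 Serpina1 genes called belong to families of near-identical copies, so which copy the UMIs came from is uncertain. These genes and Alb had both exercise libraries below both sedentary libraries. Alb is ENSMUSG00000029368 (GRCm38 chromosome 5, 90460897 to 90476602; SE 0.33, edgeR adjusted p = 0.0108). Hpx is ENSMUSG00000030895 (chromosome 7, 105591613 to 105600137; edgeR adjusted p = 0.0108) and Apoa1 is ENSMUSG00000032083 (chromosome 9, 46228580 to 46230466; edgeR adjusted p = 0.0108). Transferrin (Trf), on the hepatocyte marker list but at a mean of 733 CPM after exercise and 676 CPM in the sedentary group in Kupffer-like cells, had a log2 change of 0.12. Counted per cell, the 9 other markers differed by −2.63 on the log2 scale in Kupffer-like cells (95% interval −2.71 to −2.54, counting error only), by −2.78 in T-like cells (−3.16 to −2.42) and by −2.84 in B-like cells (−3.25 to −2.45). Both sedentary libraries lay above both exercise libraries in 11 of the 12 classes with at least 20 cells in every library, the exception being NK or ILC-like cells. The 11 include the unnamed cluster, which hepatocyte transcripts help to define, so it is not an independent case. Among smaller classes, neutrophil-like cells held 0.367 UMIs per cell in exercise replicate 2 against 0.317 in sedentary replicate 2.

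**Figure D2:**
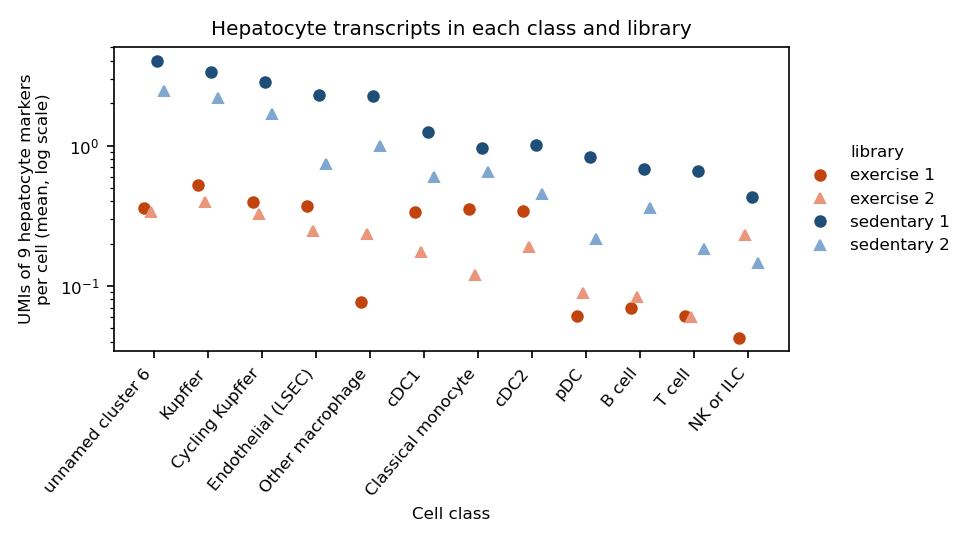
Mean UMIs of 9 hepatocyte markers per cell (y axis, log scale) in each cell class (x axis), with 1 point per library. Kupffer-like cells hold 0.523 and 0.393 UMIs per cell in the exercise libraries and 3.36 and 2.18 in the sedentary ones, and T-like cells 0.0612 and 0.0599 against 0.66 and 0.184.

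Tnfaip3 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657) fell by 1.64 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0157), from 65.5 ± 14.9 to 20.8 ± 3.74 CPM (SD, n = 2). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) fell by 0.80 (SE 0.12, edgeR adjusted p = 0.0364), from 522 ± 61.8 to 299.9 ± 0.0724 CPM (SD, n = 2). Nfkbiz (ENSMUSG00000035356, chromosome 16, 55811375 to 55838899) fell by 0.94 (SE 0.14, edgeR adjusted p = 0.0376), from 173 ± 27.1 to 90.5 ± 8.52 CPM (SD, n = 2). Rsrp1 (ENSMUSG00000037266, chromosome 4, 134923592 to 134927671) rose by 1.15 (SE 0.16, edgeR adjusted p = 0.0276). Each of these 4 genes lay on the same side in both libraries of a group. The next genes on the higher side did not pass edgeR's test: Plxna4os1, an antisense RNA whose counts cannot be parted from those of its partner without strand (log2 change 0.61, adjusted p = 0.164), Fam213b (0.64, adjusted p = 0.174), Cnpy2 (0.47, adjusted p = 0.221) and Cebpzos (0.48, adjusted p = 0.239).

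edgeR's quasi-likelihood test covered 9840 genes, of which 578 had an unadjusted p under 0.05 (219 higher, 359 lower) against 492 that chance alone would give. DESeq2 called 1 higher and 68 lower gene. Without exercise replicate 1 or without exercise replicate 2 edgeR called 0 genes (smallest adjusted p 0.0639 and 0.289, with 482 and 515 genes at an unadjusted p under 0.05). All 37 genes kept their sign. It called 1 higher and 55 lower genes without sedentary replicate 1, and 2 higher and 66 lower without sedentary replicate 2. Over all alternatives of the test the smallest adjusted p ran from 3.28e-201 to 0.289. In the Kupffer-like cells with no UMI of the 9 hepatocyte markers, an alternative chosen after seeing the data, 0 genes were called higher and 4 lower (Mup20, Serpina3k, Hbb-bt and Hba-a2, named after their values were seen), with 678 of 8102 genes at an unadjusted p under 0.05 in edgeR. DESeq2 was not run on those cells.

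None of the 24 focus genes fixed in advance for inflammation, Kupffer identity and metabolism passed edgeR's test in Kupffer-like cells. The cytokine genes Tnf and Il10 had log2 changes of −0.81 (adjusted p = 0.505) and −0.999 (adjusted p = 0.326). Each had both exercise libraries below both sedentary libraries. Group means were 6.64 CPM after exercise against 11.6 CPM for Tnf, and 5.72 against 11.5 CPM for Il10. Il1b, an inflammasome-processed cytokine, was at 0.09 and Il6 at −0.61, and the inflammasome sensor Nlrp3 at −0.22. Irg1 (also called Acod1), the enzyme that makes itaconate, was at −0.38 with 3.04 against 3.92 CPM, close to the detection limit. The endotoxin receptor Tlr4, its adaptor Myd88 and the alarmin Hmgb1 were at 0.04, −0.19 and 0.10. Of the Kupffer identity genes, the lectin Clec4f was at 0.13, the phosphatidylserine receptor Timd4 at −0.00, the scavenger receptors Marco and Cd163 at 0.13 and 0.03, and the mannose receptor Mrc1 at 0.09. Of the metabolic genes, hexokinase Hk2 was at −0.26, lactate dehydrogenase Ldha at 0.01, the glucose transporter Slc2a1 at −0.07, isocitrate dehydrogenase Idh1 at 0.09, succinate dehydrogenase Sdha at 0.01 and the hypoxia regulator Hif1a at −0.12. The oxidative stress regulator Nfe2l2 and its target heme oxygenase Hmox1 were at −0.21 and −0.30. Arg1 and Nos2 had too few counts to be tested. Leaving out 1 library turned the sign of Irg1 (0.21 without sedentary replicate 2), Il6 (0.35 without sedentary replicate 2) and Nfe2l2 (0.10 without sedentary replicate 2), and of Il1b (−0.10 without exercise replicate 2, −0.31 without sedentary replicate 1). It also turned Tlr4 (−0.15) and Mrc1 (−0.034) without exercise replicate 1, Marco (−0.12) and Cd163 (−0.042) without sedentary replicate 1, Ldha (−0.19) and Timd4 (0.12) without exercise replicate 2, and Slc2a1 (0.15) and Sdha (−0.067) without sedentary replicate 2.

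**Figure D3:**
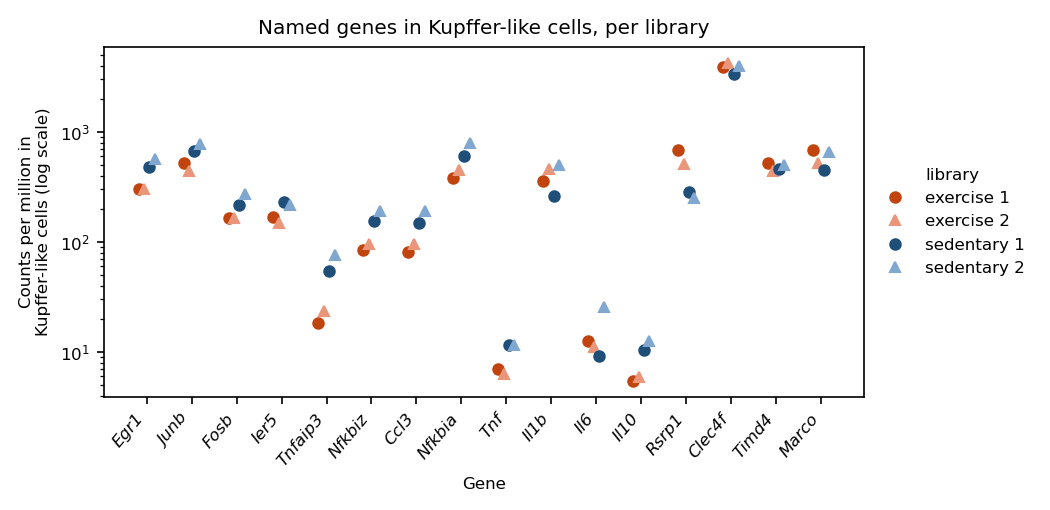
CPM of named genes (y axis, log scale) in Kupffer-like cells, with genes on the x axis and 1 point per library. Tnfaip3 lies at 18.2 and 23.5 CPM in the exercise libraries against 54.9 and 76.0 in the sedentary ones, and Rsrp1 at 685 and 508 against 287 and 250.3.

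Gene lists fixed before the data were examined, as were the groups, tests, markers and rules for naming genes, were compared in Kupffer-like cells. Immediate early and heat shock genes, which respond within minutes to stress and to tissue dissociation, had a negative change in 22 of 24 tested members, with a median of −0.49 on the log2 scale. Inflammatory cytokines and NF-kB targets had a negative change in 20 of 27 members, with a median of −0.25. Mitochondrially encoded mRNAs had a negative change in 13 of 13 members (median −0.36), whereas the change was positive in 58 of 73 nuclear-encoded oxidative phosphorylation genes (median 0.08) and in 37 of 37 ribosomal protein genes (median 0.12). Unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, had a negative change in 14 of 16 (median −0.13). In the same cells 9 of 10 hepatocyte markers were called lower (median −2.78), and the change was negative in 5 of 5 stellate or fibroblast markers (median −0.44) and 5 of 5 B cell markers (median −0.45).

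In limma's camera test with a preset correlation, these 9 of 36 lists passed, and 0 of them passed with a correlation estimated from the data. The adjusted p was 4.73e-17 for hepatocyte markers, 1.89e-06 for mitochondrially encoded mRNAs, 1.56e-05 for immediate early and heat shock genes, 8.00e-05 for NF-kB targets, 0.000846 for ribosomal proteins, 0.00736 for oxidative phosphorylation, 0.0107 for the unfolded protein response and for stellate markers, and 0.0253 for B cell markers (limma). For each of the 9 lists it was adjusted p = 0.996 with an estimated correlation, where 1 of 36 lists had an unadjusted p under 0.05. limma's fry, which tests whether the genes of a list move, on balance, in the same direction, passed 0 lists (smallest adjusted p 0.234, 2 lists at an unadjusted p under 0.05).

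Single libraries decided several of these lists in limma's camera test, and the adjusted p of each of the 9 reached 0.996 over its alternatives. Without sedentary replicate 2 the call was lost for immediate early genes and for NF-kB targets (adjusted p = 0.531 for both), the unfolded protein response (0.413) and stellate markers (0.388). Without exercise replicate 1 it was lost for immediate early genes (0.0927), the unfolded protein response (0.851) and stellate markers (0.0537). Without sedentary replicate 1 it was lost for ribosomal proteins (0.097), oxidative phosphorylation (0.123) and B cell markers (0.123), and without exercise replicate 2 for ribosomal proteins (0.324) and oxidative phosphorylation (0.0559). The lowest adjusted p over the alternatives was 8.05e-12 for immediate early genes, 4.07e-10 for NF-kB targets, 0.000267 for the unfolded protein response, 0.00359 for stellate markers, 9.54e-06 for ribosomal proteins, 0.00715 for oxidative phosphorylation and 0.000198 for B cell markers. Oxidative phosphorylation also lost its call with all Kupffer clusters together (0.715), an alternative chosen after seeing the data.

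Of the immediate early list, 1 gene was called over all genes tested, Egr1, and 10 were lower adjusted over the list alone. Junb (log2 change −0.59), Fosb (−0.59) and Ier5 (−0.50) were not past edgeR's test over all genes. Of the NF-kB list, Tnfaip3 and Nfkbiz were called over all genes, and 11 were lower and 1 higher adjusted over the list alone. The chemokine Ccl3 was at −0.92 (edgeR adjusted p = 0.0611) and the inhibitor Nfkbia at −0.74 (edgeR adjusted p = 0.142). Tnfaip3, Nfkbia and Nfkbiz are themselves known as brakes or modulators of NF-kB signalling, beside cytokine genes on the same list. Of the mitochondrial list, 0 genes were called by edgeR over all genes, where mt-Nd2 (−0.60), mt-Nd3 (−0.50), mt-Nd5 (−0.36) and mt-Nd4 (−0.36), subunits of respiratory complex I, had the smallest p, and 7 were lower adjusted over the list alone. The nuclear-encoded complex I genes Ndufb5 (0.27), Ndufs7 (0.24) and Ndufb11 (0.25), the ribosomal genes Rpl3 (0.20), Rps3 (0.15) and Rpl27 (0.15), and the folding genes Xbp1 (−0.45), Hspa5 (−0.34), Atf4 (−0.43) and Manf (−0.25) were not past edgeR's test, and 0 members of these 3 lists passed adjusted over the list alone. Of the cell type markers, Cd79a (−0.86) and Ms4a1 (−1.42) of B cells and Lrat (−1.15) and Dcn (−0.44) of stellate cells were not past the test over all genes, and 2 B cell markers and 0 stellate markers were lower adjusted over the list alone.

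The remaining metabolic lists showed no change past limma's camera test. Glycolysis had a positive change in 10 of 20 members (adjusted p = 0.996; Gpi1 0.17), the pentose phosphate pathway in 4 of 7 (adjusted p = 0.931; Pgd −0.20, Tkt −0.19), the TCA cycle in 14 of 24 (adjusted p = 0.871; Idh3g 0.32, Pdhb −0.26) and fatty acid oxidation in 13 of 20 (adjusted p = 0.703; Cpt2 0.32, Etfb 0.16). Itaconate and NRF2 response genes were positive in 5 of 14 (adjusted p = 0.597; Gsr −0.26), lipid and cholesterol handling in 13 of 20 (adjusted p = 0.527; Mylip 0.40, Apoc1 0.22), iron and heme handling in 10 of 16 (adjusted p = 0.823; Hamp −2.49, Blvrb 0.28) and hypoxia genes in 6 of 12 (adjusted p = 0.823; Ddit4 −3.71, Ankrd37 −0.91). Adjusted over the list alone, 1 iron gene and 1 hypoxia gene were lower and 0 genes of the other 6 lists passed in edgeR. Beside these lists the hepatocyte markers had a median of −2.78, and Hamp is itself a hepatocyte hormone gene.

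The remaining immune and identity lists did not pass limma's camera test either. Positive changes were found in 9 of 16 anti-inflammatory and alternative activation genes (adjusted p = 0.597; Socs3 −1.53), 11 of 24 Toll-like receptor genes (adjusted p = 0.922; Ly96 0.45, Tlr13 −0.63), 16 of 25 type I interferon genes (adjusted p = 0.869; Mx1 0.60, Irf9 0.14), 8 of 12 MHC class II genes (adjusted p = 0.996; H2-DMb2 −0.37, Ifi30 0.14) and 6 of 12 MHC class I genes (adjusted p = 0.996; Tap2 −0.27, Nlrc5 −0.38). They were found in 12 of 20 Kupffer identity genes (adjusted p = 0.823; Clec1b 0.28), 8 of 16 complement genes (adjusted p = 0.996; C3 −0.84, Serping1 −1.54), 12 of 21 phagocytosis genes (adjusted p = 0.869; Mertk −0.33, Stab1 −0.49), 18 of 27 lysosome genes (adjusted p = 0.236; Cd68 0.26, Cd63 0.80), 2 of 13 proliferation genes (adjusted p = 0.236; Mcm5 −0.68, Mcm6 −0.48) and 14 of 25 chromatin modifiers linked to trained immunity (adjusted p = 0.996; Kmt2d −0.44, Hdac9 −0.32). Adjusted over the list alone, 2 anti-inflammatory genes were lower and 0 genes of the other 10 lists passed in edgeR. The interferon list passed limma's camera upwards without exercise replicate 1 (adjusted p = 0.000587) and without sedentary replicate 2 (0.0261), and downwards without exercise replicate 2 (0.0132), with a range over its alternatives of 0.000587 to 0.996. Lysosome genes passed upwards without exercise replicate 1 (0.0342) and proliferation genes downwards without exercise replicate 2 (0.00547), with ranges up to 0.996 and 0.997. Mx1 and Cd63 turned to −0.10 and −0.092 without exercise replicate 2.

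Markers of other cell types that did not pass limma's camera test in Kupffer-like cells were endothelial (2 of 9 positive, adjusted p = 0.0587), neutrophil (2 of 5, adjusted p = 0.28, 3 lower adjusted over the list alone), classical monocyte (4 of 6, adjusted p = 0.761, 1 lower adjusted over the list alone), patrolling monocyte (6 of 7, adjusted p = 0.823), other macrophage (4 of 7, adjusted p = 0.823), cDC1 (2 of 5, adjusted p = 0.996), pDC (3 of 5, adjusted p = 0.823) and T cell markers (1 of 6, adjusted p = 0.823). Without exercise replicate 2 the endothelial (adjusted p = 0.00109), neutrophil (0.0417) and classical monocyte markers (0.0243) passed downwards, with ranges up to 0.996, 0.997 and 0.996 over the alternatives. Endothelial markers also passed downwards with doublets kept (adjusted p = 0.0289 in limma) and with clusters 0 and 1 only (0.0363), the latter chosen after seeing the data. Lists with fewer than 5 tested members were not tested. Among these, positive changes were found in 2 of 3 nuclear-retained RNAs, 3 of 4 cDC2, 1 of 3 migratory dendritic, 0 of 3 plasma cell, 0 of 3 NK or ILC, 0 of 4 erythroid and 1 of 1 platelet marker, and 0 gamma-delta T cell, basophil or mast cell and cholangiocyte markers had enough counts. The median, mean and camera direction of a list differed in sign for 9 of the 36 lists. These were glycolysis (median −0.03, mean 0.02, camera down), pentose phosphate (0.07, −0.01, down), anti-inflammatory (0.06, −0.19, down), MHC class II (0.09, 0.04, down), phagocytosis (0.06, −0.00, up), iron (0.04, −0.15, down), hypoxia (0.01, −0.37, down), chromatin modifiers (0.04, −0.01, down) and classical monocyte markers (0.04, −0.34, down).

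**Figure D4:**
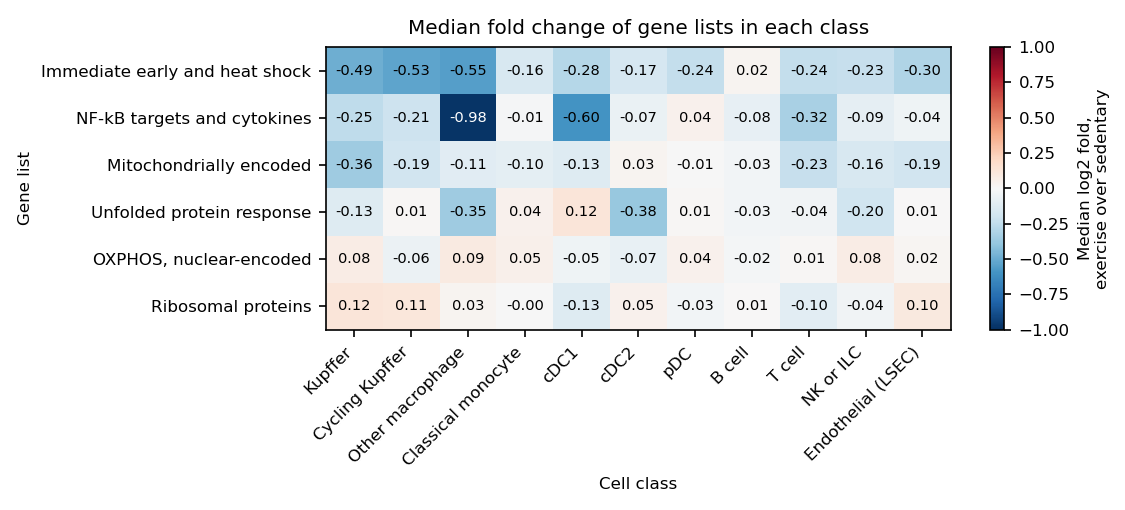
Median log2 change of 6 gene lists (y axis) in 11 cell classes (x axis), exercise over sedentary, with the value printed in each cell of the map and color for the same value. The immediate early and heat shock list lies at −0.49 in Kupffer-like cells, and its median is negative in 9 of the 10 other classes, with B-like cells at 0.02.

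In the other classes the same question was asked of 10 cell types, and hepatocyte transcripts were again among the calls. B-like cells had the most calls, with 1 gene higher and 11 lower. Rsrp1 rose by 0.86 (SE 0.13, edgeR adjusted p = 0.0162), and Tsc22d3, a glucocorticoid-induced leucine zipper gene, fell by 1.13 (SE 0.18, edgeR adjusted p = 0.0162). The RNA-binding regulator Zfp36l2 (log2 change −1.49), the PI3K inhibitor Pik3ip1 (−1.20), the phosphatase Ptpn22 (−1.45) and the histone H3f3b (−0.65) fell there as well, and so did the hepatocyte transcripts Alb (−4.30) and Ttr (−3.31), although with limma-voom these 2 calls were lost (adjusted p = 0.0568 for both; range over alternatives 7.4e-32 to 0.0568 for Alb and 4.72e-11 to 0.0568 for Ttr). In T-like cells 6 genes fell, among them the AP-1 gene Junb (−0.88, SE 0.10, edgeR adjusted p = 0.0135), the metabolic brake Txnip (−1.12, SE 0.15, edgeR adjusted p = 0.0211) and the quiescence factor Klf2 (−0.97, SE 0.14, edgeR adjusted p = 0.0335). T-like cells join 2 clusters whose mix differed between the libraries, and the test did not hold this mix constant. The cluster led by Cd8b1, Lef1, Tcf7 and Il7r held 107 of 556 and 104 of 618 T-like cells after exercise against 205 of 609 and 156 of 645 in the sedentary group. B cell markers also had negative changes in T-like cells (0 of 7 positive, median −1.43).

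Also lower in T-like cells were Il7r (−0.85), the survival cytokine receptor, Gzma (−2.42), a cytotoxic protease, and Gm8369. In NK or ILC-like cells Zfp36l2 fell by 1.45 (edgeR adjusted p = 0.038, but 0.133 with predicted doublets kept, range over alternatives 1.2e-16 to 0.133). This class joins 2 clusters, and in the larger 6 of 8 T cell markers were detected in 10% of cells, against 1 of 8 in the other. The larger held 40 of 70 and 102 of 131 of these cells after exercise. In the sedentary group it held 77 of 114 and 83 of 124. The test did not hold this mix constant, and the class may include T cells. In other macrophage-like cells Rgs1, a regulator of chemokine receptor signalling, fell by 1.48 (edgeR adjusted p = 0.0319). The LSEC-like cells had 2 lower genes, Gadd45g (−1.57, edgeR adjusted p = 0.0242), a stress-induced growth arrest gene, and the hepatocyte transcript Mup20 (−2.42, edgeR adjusted p = 0.0242). In pDC-like cells the chemokine gene Ccl5 rose by 1.74 (edgeR adjusted p = 0.0054), while H3f3b (−0.50), Zfp36l2 (−1.43) and the splicing factor Srsf5 (−0.82) fell (edgeR adjusted p = 0.041 for each). These 3 calls were lost with DESeq2 (adjusted p = 1 for each), with predicted doublets kept (edgeR adjusted p = 0.48, 0.544 and 0.337) and at most 10% mitochondrial UMIs (0.0716, 0.0918 and 0.0716). With predicted doublets kept, the Ccl5 change was 0.26 (edgeR adjusted p = 0.989, range over alternatives 1.02e-12 to 0.989). In the pDC-like cells of the main test, with predicted doublets removed, T cell markers were higher in limma's camera (5 of 5 positive, median 0.36, adjusted p = 0.0144, adjusted p = 0.896 with an estimated correlation). Cycling Kupffer-like cells had 6 lower genes, all hepatocyte transcripts, with Alb at −3.64, Mup7 at −2.99 and Apoa2 at −2.79. Every named call in these 2 paragraphs had both exercise libraries on the same side of both sedentary libraries.

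Tsc22d3 (ENSMUSG00000031431) lies on chromosome X from 140539528 to 140600659, Zfp36l2 (ENSMUSG00000045817) on chromosome 17 from 84183931 to 84187947, Junb (ENSMUSG00000052837) on chromosome 8 from 84974484 to 84978718, Txnip (ENSMUSG00000038393) on chromosome 3 from 96557957 to 96561883 and Klf2 (ENSMUSG00000055148) on chromosome 8 from 72319033 to 72321656. Rgs1 (ENSMUSG00000026358) lies on chromosome 1 from 144242296 to 144249242, Gadd45g (ENSMUSG00000021453) on chromosome 13 from 51846678 to 51848468 and Ccl5 (ENSMUSG00000035042) on chromosome 11 from 83525778 to 83530518. Across all 11 classes with Kupffer-like cells, Rsrp1 had a positive change in 11 (0.48 to 1.42, called in 2), and Tsc22d3 (−1.31 to −0.44, called in 1), Junb (−1.17 to −0.34, called in 1), Egr1 (−1.22 to −0.25, called in 1) and H3f3b (−0.71 to −0.10, called in 2) had a negative change in 11. Zfp36l2 was negative in 9 of 11 (−1.49 to 0.43, called in 3).

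Together the 10 classes gave 32 calls (2 higher, 30 lower), 11 of them hepatocyte genes. DESeq2 called 5 genes in B-like, 16 in T-like, 4 in cycling Kupffer-like, 1 in NK or ILC-like, 5 in other macrophage-like, 1 in LSEC-like and 1 in pDC-like cells. Its adjusted p was 0.795 for Tsc22d3 in B-like cells and 0.112 and 0.108 for Gadd45g and Mup20 in LSEC-like cells. The ranges over all alternatives were 2.22e-25 to 0.795 for Tsc22d3, 8.51e-07 to 0.112 for Gadd45g and 8.58e-09 to 0.149 for Mup20, whose largest value came from limma-voom. edgeR called 0 genes in classical monocyte-like, cDC1-like and cDC2-like cells, where 103, 260 and 204 genes had an unadjusted p under 0.05 and DESeq2 called 0, 2 and 0. Without exercise replicate 1, exercise replicate 2, sedentary replicate 1 and sedentary replicate 2 the 10 classes gave 288, 295, 390 and 139 calls. Rgs1 lost its call without exercise replicate 2 (edgeR adjusted p = 0.0656, range 8.19e-17 to 0.163), and in pDC-like cells Zfp36l2 and Srsf5 lost theirs without sedentary replicate 2 (edgeR adjusted p = 0.104 and 0.0519, with ranges of 2.1e-23 to 1 and 4.87e-07 to 1).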

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

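The comparison of changes between classes was run over all genes, and this gene was singled out only after the result was seen. Hspa1a, the stress-inducible HSP70 chaperone, changed differently in cDC2-like than in Kupffer-like cells by 2.94 on the log2 scale. The test was limma's on differences in log2 CPM between the 2 classes within each library (adjusted p = 0.0332 over 3467 genes). Its group means of log2 CPM differed by 2.30 in cDC2-like and −0.64 in Kupffer-like cells. Fitted within each class, the change of Hspa1a was 2.97 in cDC2-like cells (edgeR adjusted p = 0.518) and −0.79 in Kupffer-like cells (edgeR adjusted p = 0.874), so its change passed in neither class. The comparison covered 47451 gene and class pairs in 10 classes against Kupffer-like cells, adjusted within each class and not over all pairs. The Hspa1a difference was the only one past the test. The cDC2-like counts behind it were 10 and 22 UMIs in the exercise and 0 and 4 in the sedentary libraries, so it rests on few molecules, and no explanation was tested. In Kupffer-like cells the counts were 106 and 301 against 108 and 428 UMIs.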

How the results depend on the processing

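Crossed numbers, the use of all Kupffer clusters or of clusters 0 and 1 only, removal of barcodes rich in hepatocyte transcripts and thinning per cell were alternatives chosen after seeing the data. With 2 libraries per group, calls rest on few samples, and where a library is left out the lone sample is assumed to vary like the other group. Unless stated, the cause was not tested. The labels give both groups the same replicate numbers but do not say that a number marks the same animal, litter or day. Deviations of same-numbered samples had a positive correlation in 10 of 11 classes (0.0568 to 0.191, highest in Kupffer-like cells), and −0.175 in classical monocyte-like cells. The second principal component of Kupffer-like cells (31.3% of variance) parted replicates 1 (15.7 and 12.8) from replicates 2 (−10.3 and −18.2). This hint from the data was not taken as a paired design. With the replicate block, edgeR called 13 higher and 155 lower genes in Kupffer-like cells (1 and 36 without it), 388 in other classes (32), 11 gene lists (9, to which endothelial markers at adjusted p = 0.0269 and neutrophil markers at adjusted p = 0.0185 were added in limma, and 0 lists with the block and an estimated correlation, smallest adjusted p 0.98) and 3 class shares (2), and all 37 Kupffer calls were among them. With crossed numbers 61 lower Kupffer genes and 58 genes of other classes were called.

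Genes higher in Kupffer-like cells numbered 20 with no filter on low counts (15271 genes tested, against 9840 with it), and 0 with marker-positive cells or without hepatocyte marker UMIs. Genes lower numbered 68 with DESeq2, 205 with no filter, 15 with limma-voom, 22 with marker-positive cells and 4 without hepatocyte marker UMIs, and 0 to 66 with 1 library left out. Calls in other classes numbered 392 with no filter, 60 with doublets kept and 139 to 390 with 1 library left out. Gene lists past the test numbered 0 with an estimated correlation and 0 with fry. The estimated correlation also missed a simulated shift, so its 0 does not show that the lists are unchanged. That simulation does not back the preset calls either. Class shares past edgeR's test numbered 1 with TMM over classes, 1 at most 10% mitochondrial UMIs, and 0 among named immune classes, with doublets kept, with at least 1000 UMIs and 500 genes, at resolution 0.5 and with centring per library (each with 2 classes at an unadjusted p under 0.05), and 0 to 4 with 1 library left out. The 0s came from edgeR or limma, with the other tool's counts in the text where it was run.

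Some changes in Kupffer-like cells that were not past the test turned sign. With marker-positive cells these were Il1b (−0.0050), Tlr4 (−0.056) and Cd163 (−0.019). Without hepatocyte marker UMIs they were Il1b (−0.053), Mrc1 (−0.042), Tlr4 (−0.17), Sdha (−0.036), Etfb (−0.063), C3 (0.18) and Manf (0.042). With all Kupffer clusters they were Tlr4 (−0.030), Ldha (−0.020) and Slc2a1 (0.0020), and with clusters 0 and 1 only Sdha (−0.045). With every cell thinned they were Tlr4 (−0.013), Slc2a1 (0.12) and Cpt2 (−0.15), and thinned to the shallowest library Slc2a1 (0.10) and Colec11 (0.18). At most 10% mitochondrial UMIs gave −0.030 for Ldha. Timd4, near 0, was at 0.013 with no filter, 0.017 with doublets kept, 0.0079 at resolution 0.5, 0.0053 with centring per library, 0.0024 with clusters 0 and 1 and 0.0028 without the top barcodes. With TMM over classes the shares of cDC1 and cDC2 turned to 0.033 and 0.034.

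With 1 library left out, the lowest and highest changes were −0.75 and 0.21 for Irg1, −0.31 and 0.64 for Il1b, −1.14 and 0.35 for Il6, −0.034 and 0.22 for Mrc1, −0.15 and 0.22 for Tlr4, −0.13 and 0.12 for Timd4, −0.12 and 0.42 for Marco, −0.042 and 0.10 for Cd163, −0.19 and 0.19 for Ldha, −0.067 and 0.083 for Sdha, −0.25 and 0.15 for Slc2a1, −0.46 and 0.10 for Nfe2l2, −0.10 and 0.99 for Mx1, −0.092 and 1.46 for Cd63, −0.93 and 0.15 for Fcmr, and −0.62 and 0.12 for Colec11. For shares they were −0.37 and 0.13 (cDC1), −0.30 and 0.17 (cDC2), −0.59 and 0.076 (classical monocyte), −0.31 and 0.48 (cycling cDC1), −0.39 and 0.81 (cycling Kupffer), −1.10 and 0.034 (cycling T cell), −0.21 and 0.22 (LSEC), −0.34 and 0.042 (NK or ILC), −1.08 and 0.42 (stellate) and −0.12 and 0.25 (T cell). Over the other alternatives, the named Kupffer genes gave 1781 values with the same direction and side of the threshold, 51 newly past it and 20 no longer past it, and named genes of other classes 162 and 18 no longer past it. Lists past the test gave 44 such values and 19 no longer past it, and class shares 143, with 1 newly past the test and 11 no longer past it.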

Other observations

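The lists of glucocorticoid-induced and clock genes, the joint use of the 5 lymphocyte genes, the list medians in cells without hepatocyte marker UMIs, the tests of equal free RNA and of Kupffer-only RNA, and the test of sedentary replicate 2 alone were chosen only after the results they bear on were seen. Outside Kupffer-like cells, classical monocyte-like cells had higher lysosome genes (21 of 25 positive, median 0.33 on the log2 scale, limma camera adjusted p = 0.00314) and higher lipid and cholesterol handling genes (10 of 11 positive, median 0.53, adjusted p = 0.026), with lower anti-inflammatory genes (0 of 11 positive, median −0.38, adjusted p = 0.026). For each of the 3 it was adjusted p = 0.893 with an estimated correlation. MHC class II genes, which present antigen to helper T cells, were lower in LSEC-like cells (1 of 8 positive, median −0.59, adjusted p = 0.00732, adjusted p = 0.907 with an estimated correlation) and in T-like cells (2 of 12 positive, median −0.57, adjusted p = 0.00186, adjusted p = 0.869 with an estimated correlation). In T-like cells B cell markers were also lower (0 of 7 positive, median −1.43, limma camera adjusted p = 2.43e-08, adjusted p = 0.869 with an estimated correlation), and so were ribosomal protein genes (0 of 37 positive, median −0.10, adjusted p = 0.0293, adjusted p = 0.869 with an estimated correlation). Whether B cell RNA or the differing mix of clusters lies behind the MHC class II values in T-like cells was not tested.

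Dendritic and macrophage classes differed in which lists passed, though differences between classes were not tested for lists. Unfolded protein response genes were lower in cDC2-like cells (1 of 14 positive, median −0.38, limma camera adjusted p = 0.000196, adjusted p = 0.957 with an estimated correlation). NF-kB targets were lower in cDC1-like cells (1 of 14 positive, median −0.60, adjusted p = 0.016, adjusted p = 0.956 with an estimated correlation), where ribosomal protein genes were lower too (median −0.13, adjusted p = 0.0368, adjusted p = 0.956 with an estimated correlation). Other macrophage-like cells had lower NF-kB targets (1 of 16 positive, median −0.98, adjusted p = 2.2e-09, adjusted p = 0.869 with an estimated correlation) and lower immediate early genes (1 of 20 positive, median −0.55, adjusted p = 1.2e-07, adjusted p = 0.869 with an estimated correlation). In cycling Kupffer-like cells the same lists had medians of −0.21 (adjusted p = 0.00507, adjusted p = 0.898 with an estimated correlation) and −0.53 (adjusted p = 3.43e-05, adjusted p = 0.898 with an estimated correlation). The immediate early list was lower past camera in 6 of the 10 other classes, the NF-kB list in 3, and hepatocyte markers in all 4 classes where they could be tested. With an estimated correlation 0 of these 13 calls passed in limma (smallest adjusted p 0.869). Complement genes were lower in LSEC-like cells (1 of 10 positive, median −0.24, adjusted p = 0.0438, adjusted p = 0.907 with an estimated correlation).

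Hepatocyte transcripts were lower after exercise in Kupffer-like cells, and a free pool of RNA from lysed hepatocytes at an equal level in every droplet cannot be the whole of it, since Kupffer-like cells held at least 4.71 times as many marker UMIs as T- or B-like cells in each library. Uptake or expression by Kupffer-like cells alone cannot be the whole of it either, because the markers had a median change of −2.89 or lower in T- and B-like cells. Barcodes that also hold a hepatocyte are not the main source, as the change was −2.94 in CPM without the 1 percent of barcodes richest in markers. What stays open is that the sedentary suspensions may have held more hepatocyte RNA, some of it bound or taken up by Kupffer-like cells, from a difference in cell isolation or in the livers themselves, and the design cannot part these. A biological effect of exercise on the release or uptake of hepatocyte RNA was not tested.

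The immediate early and NF-kB lists were lower in Kupffer-like cells in limma's camera test with a preset correlation (adjusted p = 0.996 with an estimated correlation, adjusted p = 0.531 without sedentary replicate 2, for both), and only Egr1, Tnfaip3 and Nfkbiz passed over all genes. In 9 of the 10 other classes the immediate early list also had a negative median, which is in line with a step or state shared by all cells of a library. In Kupffer-like cells without hepatocyte marker UMIs, Egr1, Tnfaip3 and Nfkbiz had a median of −0.85. The medians of all tested members there were −0.43 for the immediate early and −0.32 for the NF-kB list. That subset held 799 and 1246 cells after exercise but only 174 and 268 in the sedentary group. The 4 genes called lower in it were Mup20, Serpina3k, Hbb-bt and Hba-a2, so it still differed in hepatocyte transcripts. Egr1, Tnfaip3 and Nfkbiz were also picked as lower in these libraries, so these values cannot exclude free hepatocyte RNA. After thinning every cell, the median of the immediate early list was −0.46. Random thinning keeps the expected proportions of genes, so this cannot decide whether the lower depth of the sedentary libraries played a part. The time from harvest to capture, which is known to induce these genes during digestion, and a systemic effect of exercise both stay open, since either may act on all cells of a sample.

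Tsc22d3, Zfp36l2, Txnip, Pik3ip1 and Klf2 had a median change of −1.12 in T-like, −1.13 in B-like and −0.012 in Kupffer-like cells, but not all 5 moved. Klf2 was at −0.029 and Txnip at −0.51 in B-like cells, neither past the test. In T-like cells only Klf2 and Txnip of the 5 passed it. Kupffer-like cells had Tsc22d3 at −0.44, Zfp36l2 at 0.43 and Klf2 at 0.32, also not past the test. No gene changed differently in lymphocytes than in Kupffer-like cells past limma's test of within-library differences. Lower glucocorticoid exposure of the exercise samples is a candidate explanation: other glucocorticoid-induced genes, such as Fkbp5, Per1 and Sgk1, had medians of −0.38 in T-like and −0.53 in B-like cells, and the larger limma camera p of the 2 classes was 0.0448 (p = 0.279 and 0.183 with an estimated correlation). In Kupffer-like cells that median was −0.54. No member of that list passed edgeR's test in T- or B-like cells. In T-like cells Zbtb16 (0.34), Arl4d (0.37) and Cited2 (0.10) rose while the other tested members fell. In NK or ILC-like cells, where Zfp36l2 also fell, the tested members were Cited2 (0.32), Smap2 (0.0072) and Arl4d (−0.013). A difference in the time of harvest cannot be told apart from lower glucocorticoid exposure. Clock output genes moved apart from clock genes of the opposite phase by 0.42 in Kupffer-like, 0.69 in T-like and only 0.060 in B-like cells, on few tested genes. Sedentary replicate 2 as the whole cause is argued against, since the median without it was −0.88 or lower in both lymphocyte classes and all 5 genes were at −0.66 or lower in T-like cells. The genes were picked as lower with all libraries, so the size of these values is not an independent estimate. The mix of clusters within T-like cells, which differed between the groups, was not tested as an explanation.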
